A study of Mus musculus with 6 samples.

How the data were processed

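RNA from mouse embryonic stem cells was measured on 6 single-colour Affymetrix arrays, 3 of control cells and 3 of cells in which Trim71 had been knocked down. Per the labels' protocols, cells received a mixture of 3 siRNAs against Trim71 or a non-targeting siRNA with a lipid transfection reagent and were harvested after 72 h. The titles and genotype fields describe the control arrays as wild type and the series title calls them parental, so whether those cells received the non-targeting siRNA is left open by the labels. The siRNA sequences were not used here, so changes from effects of the siRNAs on other transcripts cannot be separated from those that follow the loss of Trim71. Per the labels' protocols, 100 ng of total RNA was amplified with a whole-transcript kit, and the sense-strand cDNA was fragmented and labelled with biotin.

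The values used were the deposited series table, which holds log2 expression for each probe set and array. Per the submitters' processing notes, RMA and the affy package were used, and their versions are not given in the sources used here. RMA corrects the background, quantile normalizes the arrays and summarizes the probes of a set. After such scaling, a change shared by most genes could not be seen. The deposited values carry no detection call, so no gene was called present or absent, and changes of dim probe sets understate the change of the transcript. The number of arrays limits the precision, and the labels do not say whether the replicates were separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

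Probe sets were named from GEO's platform annotation, which can hold old names. Of 34760 probe sets, 21640 had 1 gene symbol, 1321 had several and 11799 were unnamed here. Of those with 1 symbol, 21553 matched a RefSeq gene table by Entrez identifier, and 0 symbols needed an update. Genes were named only from probe sets with 1 symbol. For the 954 genes with several such probe sets, the one with the highest mean over all 6 arrays was used, which left 19937 genes. No intensity filter was applied. No genome build was given in the sources used here, so no coordinates are printed.

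Group was the only term of a linear model fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings). P-values were adjusted by the Benjamini-Hochberg method over the 19937 genes, and an adjusted p under 0.05 was called a change. Errors of log2 fold changes are standard errors of this fit. For Trim71 an exact two-sided permutation test was added. Gene lists were tested with camera from limma, with a preset inter-gene correlation of 0.01 and adjustment over 30 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance without a comparison with other genes, stand beside it. Of 712 list entries, 636 were measured. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and permutation tests over genes with scipy 1.17.1 and 100000 resamples.

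The groups, the fit, the 30 lists, the naming rule and the alternatives were fixed before the data were examined. Named genes are Trim71 and, in each direction, the 12 genes with the largest log2 fold change among those called whose 3 control and 3 knockdown values do not overlap. Predicted or uncharacterised genes, small RNA genes and olfactory or vomeronasal receptors were left out of that ranking. In each list up to 4 members with the largest absolute moderated statistic may be named, plus every called member of the lists of reported Trim71 targets and of cell cycle inhibitors. Other genes in the text were chosen after their values were seen and are introduced as such.

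The fit was tested on simulated data in which 200 of 19937 genes, and the genes of 1 shifted list, were changed between groups of 3 arrays. It recovered 82.0% of genes changed 1.5-fold and 98.0% of genes changed 2-fold. Of its calls, 6.03% were unchanged genes. The simulated noise was independent between genes and alike on all arrays, without an array that stands apart. These rates therefore need not hold for the real calls, most of which changed less than 1.5-fold.

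The alternatives were the replicate number as a block, each array left out in turn, the bright part of the probe sets, a trended and robust prior, array weights and the mean of all probe sets of a gene. The others were quantile normalization repeated, arrays centred on their medians, no variance moderation, all probe sets including those without 1 symbol, a minimum change of 1.5-fold, an adjusted p under 0.01, an estimated correlation, and fry.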

Results

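Trim71, also called Lin41, is an RNA-binding protein and ubiquitin ligase of early embryos and embryonic stem cells. The arrays compared the transcripts of mouse embryonic stem cells with and without its knockdown by siRNA, in 3 arrays per group. The 3 control arrays had median log2 signals of 6.26, and knockdown arrays 1 to 3 had medians of 6.27, 6.30 and 6.31. Knockdown array 3 stood apart. Its upper quartile was 8.42 against 8.32 to 8.35 on the other 5 arrays, and its root mean square deviation from its group mean was 0.11, against 0.07 to 0.09 elsewhere. No pair of arrays held the same values.

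The first comparison asked how far the targeted transcript was reduced. Trim71 fell in the knockdown cells, from a log2 level of 10.50 ± 0.018 (SD, n = 3) to 8.98 ± 0.025 (SD, n = 3). The remaining Trim71 signal was 34.9% of the control level (95% confidence interval 32.4 to 37.5%), a level 2.87-fold lower. The control arrays read 10.48, 10.50 and 10.51, and the knockdown arrays read 9.00, 8.95 and 8.98. The log2 fold change was −1.52 with a standard error of 0.045 and an adjusted p of 2.8e-05 in limma. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays can give.

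The next comparison asked which other transcripts differed. Prkch, which encodes the eta isoform of protein kinase C, rose most among named genes (2.63-fold, log2 fold change 1.39 ± 0.058 SE, adjusted p = 0.000199), and Zp3, a glycoprotein of the egg coat, fell most after Trim71 (log2 fold change −1.03 ± 0.048 SE, adjusted p = 0.00028). Among 19937 genes, 675 were higher and 428 lower after the knockdown, 5.53% of those tested. Most changes were small. The median change was 1.26-fold for higher genes and 1.27-fold for lower genes, 62 genes were higher and 43 lower by at least 1.5-fold, and 4 were higher and 3 lower by at least 2-fold. The values of the groups did not overlap for 25.5% of genes, where exchangeable arrays give 10% on average over all splits. All genes share the same 6 arrays, so the excess over 10% is no measure of chance. Higher genes made up 61.2% of the calls, but the split depended on scaling and on 1 array. It was 779 higher and 763 lower after a repeated quantile normalization, 527 and 616 with arrays centred on their medians, and 603 and 699 without knockdown array 3. Without control array 1, 2 or 3 the counts were 148 and 101, 179 and 102, and 228 and 137, and without knockdown array 1 or 2 they were 449 and 205, and 227 and 117. With each of the 6 arrays left out in turn, 134 higher and 84 lower genes were called every time.

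**Figure D1:**
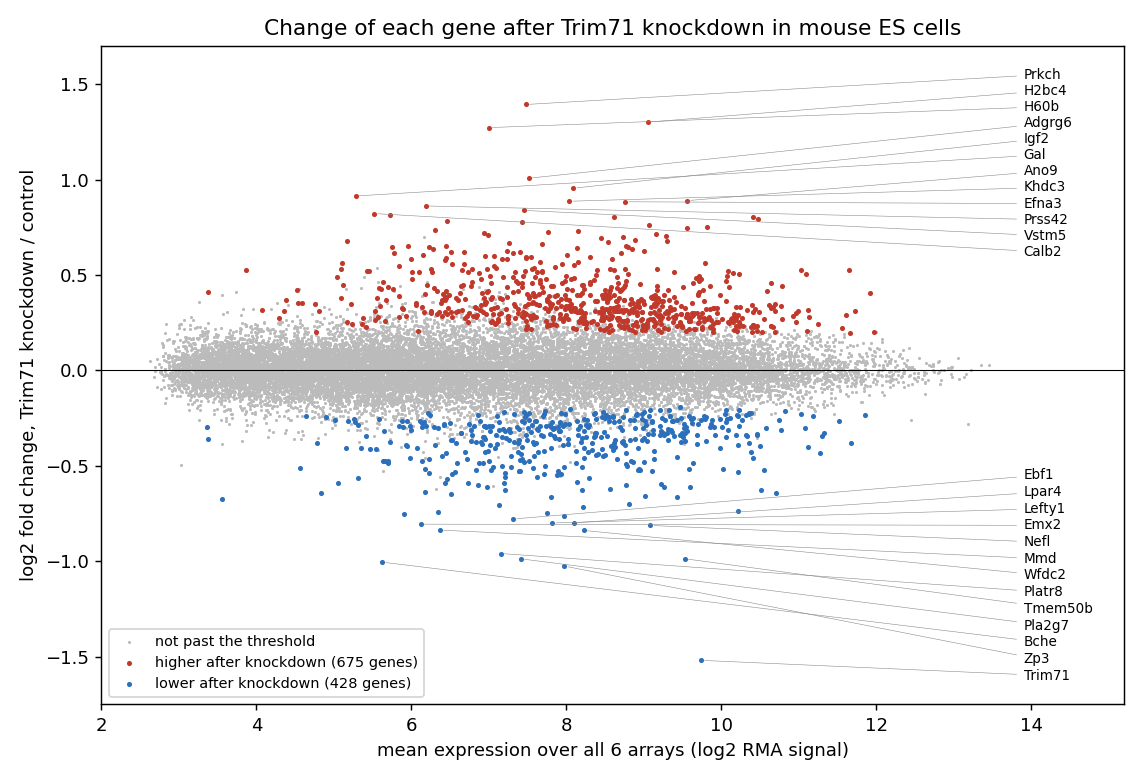
Log2 fold change of each gene (knockdown minus control, vertical axis) against its mean log2 signal over the 6 arrays (horizontal axis), with called genes in colour and the leading genes named. Trim71 lies lowest at −1.52 and Prkch highest at 1.39.

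The 12 leading higher genes rose between 1.77-fold and 2.63-fold. After Prkch came H2bc4, a histone H2B gene, with a log2 fold change of 1.30 ± 0.072 SE. Its family holds near-identical copies that probes may not separate. H60b, a ligand of the natural killer receptor NKG2D, rose by 1.27 ± 0.13 SE, and the adhesion receptor gene Adgrg6 by 1.01 ± 0.066 SE. Igf2, an imprinted fetal growth factor, rose 1.94-fold from a log2 level of 7.61 to 8.57. The neuropeptide gene Gal rose by 0.91 ± 0.071 SE. Khdc3, a maternal-effect gene of oocytes and early embryos, rose by 0.89, and Efna3, an ephrin, by 0.88. The others were Ano9 at 0.89, Prss42 at 0.86, Vstm5 at 0.84 and Calb2, which encodes the calcium-binding protein calretinin, at 0.82.

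Among the 12 leading lower genes other than the target, Zp3 went from a log2 level of 8.49 to 7.46. Bche, a cholinesterase, had a log2 fold change of −1.01 ± 0.10 SE, and Pla2g7, a secreted phospholipase, one of −0.99 ± 0.097 SE. Tmem50b went from 10.02 to 9.03. Lefty1, a secreted antagonist and transcriptional target of Nodal signalling, had a log2 fold change of −0.80. Nefl, a neurofilament gene, fell by 0.81, and Emx2, a homeobox gene of the forebrain and urogenital tract, fell by 0.81. Ebf1, a transcription factor of B cell and mesenchymal development, fell by 0.78. The remaining members were Platr8, a noncoding RNA, at −0.96, Wfdc2 at −0.84, Mmd at −0.84 and Lpar4 at −0.80. All 24 leading genes were called with each array left out in turn. Without variance moderation 8 of the 24 lost the call, H60b, Vstm5, Calb2, Bche, Pla2g7, Platr8, Nefl and Emx2.

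The gene lists asked whether known groups moved together. Of 30 lists, 6 were called with the preset correlation, all upward. With an estimated correlation 0 were called, and 1 list had an unadjusted p under 0.05. That version of camera also has far fewer degrees of freedom. The unadjusted camera p of the 2-cell-like list went from 0.00291 to 0.0369 although its estimated correlation was −0.046. The 0 calls therefore do not show that correlation between genes undid the 6. Fry called 10. The 6 became 2 without control array 3, 2 without knockdown array 2 and 0 without knockdown array 3, where 7 had an unadjusted p under 0.05. They became 0 with array weights (7 unadjusted), 0 in the bright part of the probe sets (5 of 28 unadjusted) and 1, the naive list, without moderation. Of 96 named genes called with all arrays, 46 stayed called with any array left out, and the other 50 reached adjusted p-values of up to 0.185 in such a fit of 5 arrays.

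Genes reported as Trim71 targets were measured for 11 of the 12 listed, all but Cdkn1a, which had no probe set with 1 gene symbol. Some may have been picked by the study on these arrays, so their direction is not independent evidence. Of the 11, 5 rose and 2 fell, and 6 rose and 2 fell when adjusted over the list alone. Plxnb2, a semaphorin receptor, rose by 0.75 ± 0.055 SE (adjusted p = 0.00169), Inhbb, a subunit of activin and inhibin, by 0.69 ± 0.068 SE (adjusted p = 0.00296), and Mbnl1, a splicing regulator, by 0.67 ± 0.055 SE (adjusted p = 0.00185). Rbl1, which encodes the retinoblastoma-related protein p107, rose by 0.40, and the repressor gene E2f7 by 0.27. Egr1, an immediate early transcription factor, had a log2 fold change of −0.48, and Nab1, a corepressor of Egr proteins, one of −0.24. Rbl2 at 0.26 (adjusted p = 0.126), Hoxa5 at 0.04, Nab2 at −0.03 and Ago2 at −0.08 did not pass, and are named after their values were seen. Hoxa5 was dim, with a mean log2 level of 3.95, so a change of it could hardly be seen. Plxnb2, Inhbb, Mbnl1 and Egr1 stayed called with any array left out, while Rbl1, E2f7 and Nab1 reached adjusted p-values of 0.068, 0.131 and 0.183. The list mean was 0.21 (adjusted p = 0.0448), with an adjusted p = 0.757 with an estimated correlation. That estimate was −0.034, under the preset 0.01, so a larger correlation was not what raised the p of this list. The fewer degrees of freedom of that version of camera raised it, from an unadjusted 0.00895 to 0.0518. The adjusted p was 0.0501 without control array 3, 0.07 without knockdown array 2 and 0.117 without knockdown array 3.

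**Figure D2:**
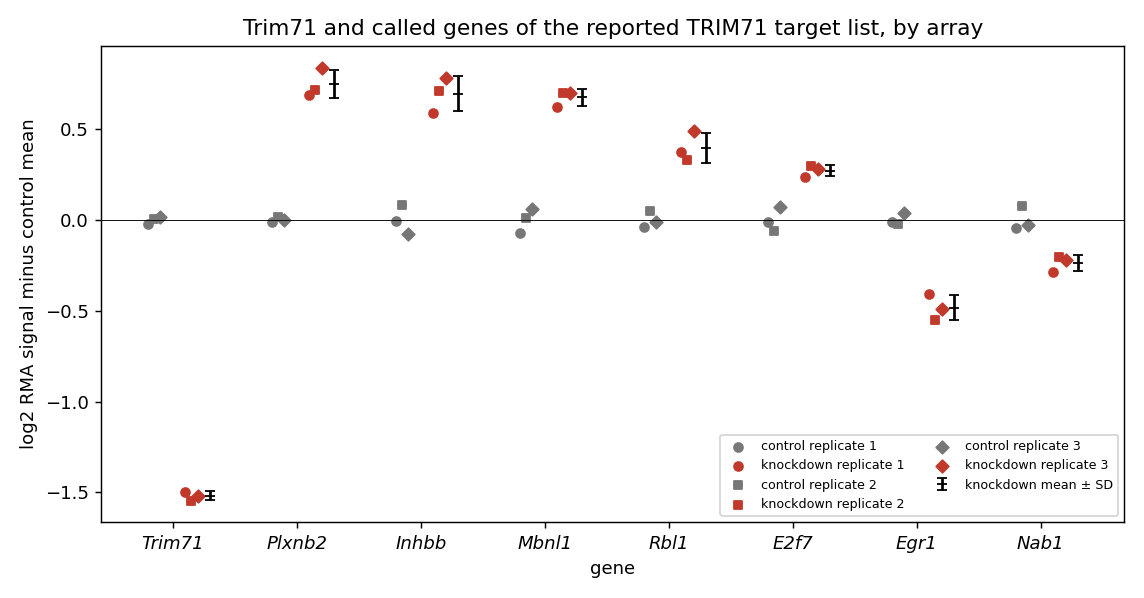
Log2 signal of each array minus the control mean (vertical axis) for Trim71 and the 7 called genes of the reported target list (horizontal axis), with a point per control (grey) and knockdown (red) array and a bar for the knockdown mean ± SD (n = 3). Trim71, Egr1 and Nab1 lie below the controls on all 3 knockdown arrays, and Plxnb2, Inhbb, Mbnl1, Rbl1 and E2f7 lie above them.

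Cell cycle inhibitors were measured for 19 of the 20 listed genes, again all but Cdkn1a. Of these, 5 rose and 1 fell, against 7 and 2 when adjusted over the list alone. Rbl1 and E2f7, which stand in both lists, rose together with Btg2, an antiproliferative gene, at 0.39, Gadd45a, a DNA damage response gene, at 0.32, and the retinoblastoma gene Rb1 at 0.24. Cdkn1b, the inhibitor p27, went the other way at −0.48 ± 0.067 SE (adjusted p = 0.0103). None of these 6 calls in limma held in all 6 fits with an array left out, and the highest adjusted p was 0.142, for Rb1. The list mean was 0.09 (adjusted p = 0.0448), with an adjusted p = 0.778 with an estimated correlation. The adjusted p was 0.0893 without control array 3, 0.0547 without knockdown array 2 and 0.19 without knockdown array 3. Targets of the tumour suppressor p53 included 2 genes that rose of 27 measured, Btg2 and the DNA polymerase gene Polk at 0.31, and 5 when adjusted over the list alone. Cdkn1a, Bax and Gdf15 of the p53 list were not measured. Mdm2, which encodes the ligase that degrades p53, was at 0.22 with an adjusted p of 0.0597. With an array left out, Btg2 reached 0.0987 and Polk 0.152. The p53 list mean was 0.08 (adjusted p = 0.0448), with an adjusted p = 0.778 with an estimated correlation. The adjusted p of the p53 list was 0.0893 without control array 3, 0.053 without knockdown array 2 and 0.204 without knockdown array 3, and fry gave 0.0811.

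Naive pluripotency genes, active in the preimplantation epiblast, rose for 4 of 16 measured and fell for 1, against 9 and 1 when adjusted over the list alone. The transcription factor gene Klf4 rose by 0.36 ± 0.057 SE (adjusted p = 0.0141), Tet2, which encodes an enzyme that oxidises methylcytosine, by 0.34, and Klf2 by 0.22. Tcl1, a cofactor of the kinase Akt, was at −0.46 ± 0.057 SE and was the 1 member called with any array left out. Klf4, Tet2 and Klf2 reached 0.068, 0.101 and 0.176 with an array left out. The list mean was 0.12 (adjusted p = 0.0195), with an adjusted p = 0.778 with an estimated correlation and 0.0923 without knockdown array 3. Core pluripotency genes rose for 3 of 19 and fell for 1, the same counts as when adjusted over the list alone, and the list was not called by camera (adjusted p = 0.191) or fry (adjusted p = 0.0811). Fgf4, a growth factor secreted by these cells, rose by 0.31, Zfp42 by 0.25 and Jarid2, a subunit of Polycomb repressive complex 2, by 0.20, while Lin28a, which blocks let-7 maturation, was at −0.26. None of these 4 core genes held in all 6 fits with an array left out, and Jarid2 reached the highest adjusted p, 0.161. Genes of the primed, later epiblast were not called as a list by camera (adjusted p = 0.152) but were called lower by fry (adjusted p = 0.0472), with 2 higher and 4 lower of 17 (2 and 6 when adjusted over the list alone), among them the DNA methyltransferase genes Dnmt3b at −0.53 and Dnmt3a at −0.35 and the transcription factor gene Zic2 at −0.45. The 2 higher genes were Lef1, a nuclear effector of Wnt signalling, at 0.38 and the growth factor gene Fgf5, chosen after its value was seen, at 0.27. Dnmt3b stayed called with any array left out, while Dnmt3a, Zic2 and Lef1 reached 0.0688, 0.0584 and 0.12 and Fgf5 was not called in all 6 such fits.

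Trophectoderm genes, active in the outer layer of the blastocyst, rose for 3 of 18 and fell for 0, and 4 rose when adjusted over the list alone. Tfap2c, an AP-2 transcription factor, rose by 0.53 ± 0.067 SE (adjusted p = 0.00723), the receptor gene Fgfr2 by 0.49 ± 0.05 SE (adjusted p = 0.00323) and Gata2 by 0.38 ± 0.05 SE (adjusted p = 0.00793), and each stayed called with any array left out. The list mean was 0.12 (adjusted p = 0.0448), with an adjusted p = 0.757 with an estimated correlation. The adjusted p was 0.0744 without knockdown array 2 and 0.0923 without knockdown array 3. For genes of 2-cell-like cells, 8 genes were measured of 18 list entries, without Zscan4c, Zscan4d, Zscan4f or Duxf3. The 8 were dim, with mean log2 levels from 3.82 to 6.17. Of these, 1 rose, and 2 when adjusted over the list alone. This was Zfp352 at 0.43 ± 0.091 SE (adjusted p = 0.0395), which reached an adjusted p of 0.153 with an array left out, while Gm5662 at 0.70 ± 0.17 SE did not pass (adjusted p = 0.0649). The 2-cell-like list mean was 0.27 (adjusted p = 0.0437), with an adjusted p = 0.757 with an estimated correlation, 0.0501 without control array 3 and 0.0923 without knockdown array 3. Its estimated correlation was −0.046, also under the preset 0.01, so here too the fewer degrees of freedom raised the p.

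**Figure D3:**
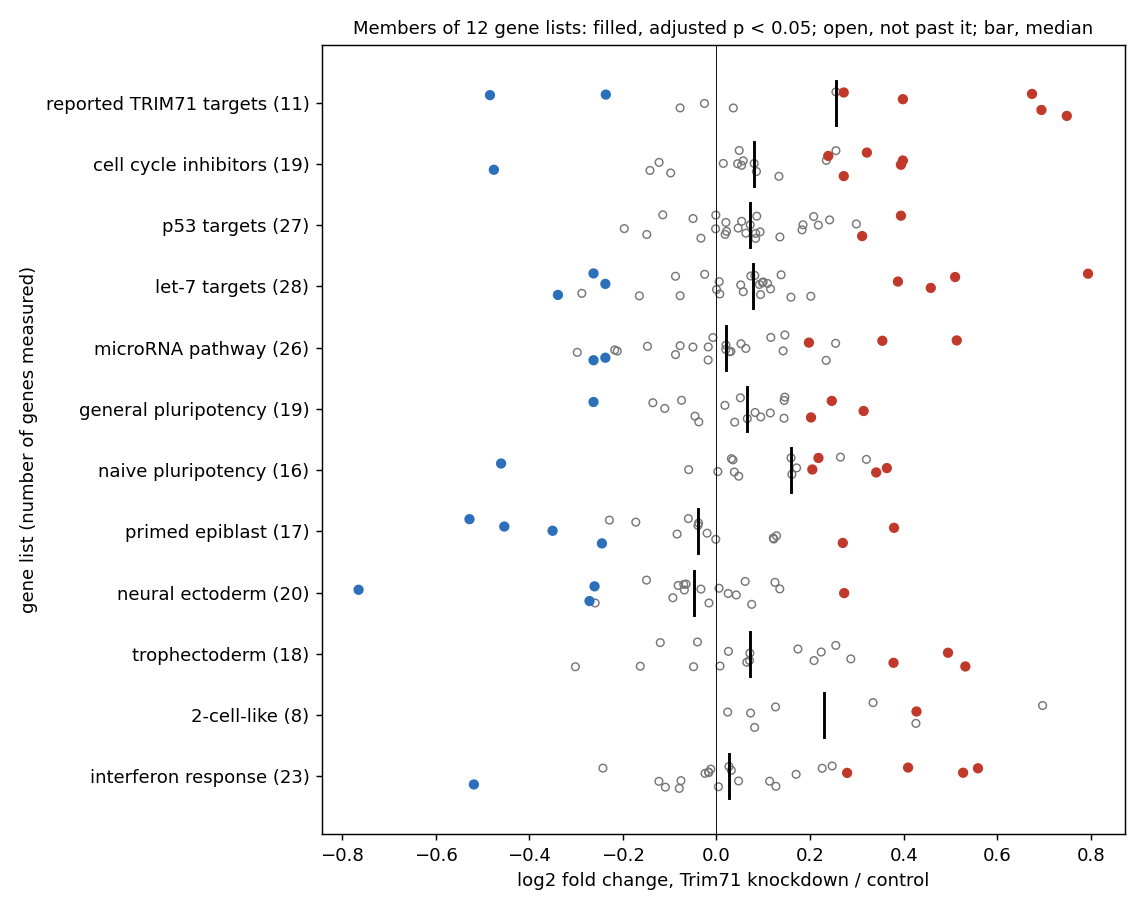
Log2 fold change (horizontal axis, knockdown over control) of each measured member of 12 gene lists (vertical axis, with the number measured), filled where the gene was called (red higher, blue lower), open where it was not, with a bar at the list median. The medians of the reported targets and of the naive list lie at 0.26 and 0.16, and called members of the let-7 list lie on both sides of 0.

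Targets of the let-7 microRNAs went both ways, with 4 higher and 3 lower of 28 (6 and 4 when adjusted over the list alone), and the list was not called by camera (adjusted p = 0.177) but was called by fry (adjusted p = 0.0472). Ccnd2, which encodes the G1 cyclin D2, rose by 0.79 ± 0.059 SE (adjusted p = 0.00171), Thbs1, a matrix glycoprotein, by 0.51, Mycn by 0.46 and Arid3a by 0.39, and all 4 stayed called with any array left out. Nr6a1, a germ cell nuclear receptor gene, was at −0.34 and was chosen after its value was seen, as it is 1 of the 3 lower members with Lin28a and Lin28b. MicroRNA pathway genes were not called as a list by camera (adjusted p = 0.959) or fry (adjusted p = 0.884), with 3 higher and 2 lower of 26 (6 and 5 when adjusted over the list alone). Trim32, a related ligase that binds Argonaute, rose by 0.51 and the silencing scaffold gene Tnrc6a by 0.35, while Lin28a and its paralog Lin28b were lower, Lin28b at −0.24. None of these microRNA pathway calls held in all 6 fits with an array left out, with adjusted p-values of up to 0.162 for Lin28b. Interferon response genes rose for 4 of 23 and fell for 1 (7 and 2 when adjusted over the list alone), and the list was not called by camera (adjusted p = 0.244) but was called by fry (adjusted p = 0.0472). Oas1a, an antiviral synthetase, rose by 0.56 and the membrane protein gene Ifitm3 by 0.53, while Ddx58, which encodes the RNA sensor RIG-I, was at −0.52, and these 3 stayed called with any array left out. Oasl2 at 0.28 reached 0.132.

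Of the remaining lists none was called by camera, and fry called the heat shock and replicative histone lists. Neural genes were higher for 1 and lower for 3 of 20 (1 and 4 when adjusted over the list alone, adjusted p = 0.172), led by the eye and brain regulator Pax6 at −0.76. Mesoderm genes were higher for 1 of 20 (0 over the list alone, adjusted p = 0.592), Snai1 at 0.23, and endoderm genes lower for 1 of 20 (1, adjusted p = 0.873), Gpc3 at −0.28. Germline genes were higher for 2 of 21 (3 higher and 1 lower, adjusted p = 0.403), Mael at 0.28 and Tex101 at 0.24. Replicative histone genes were higher for 2 of 11 (4, adjusted p = 0.0881 in camera and 0.0439 in fry), H2bc4 at 1.30 and H1f2 at 0.36. The mean of the histone list was 0.19 and its median 0.04, so the mean rests largely on H2bc4. Genes of the G1/S transition were higher for 2 of 27 (2, adjusted p = 0.663), Ccne2 at 0.44 and Ccnd3 at 0.29. Genes of mitosis were called for 0 of 25 in limma (0, adjusted p = 0.191), with 3 at an unadjusted p under 0.05 and 4 calls with a trended prior. Targets of Nodal, BMP and Wnt signals were higher for 5 and lower for 2 of 21 (6 and 5, adjusted p = 0.873), with Lefty1, Inhbb, the BMP antagonist Smad6 at 0.44 and Id3 at 0.35. Genes of the FGF and ERK response were higher for 2 and lower for 2 of 20 (6 and 7, adjusted p = 0.406), with Egr1, Etv4 at −0.29, Junb at 0.26 and Spred1 at 0.23. Imprinted genes were higher for 2 and lower for 1 of 22 (3 and 2, adjusted p = 0.985), with Igf2, Zdbf2 at 0.42 and Grb10 at −0.30.

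Genes of glycolysis and hypoxia were higher for 3 and lower for 2 of 27 (4 and 4 when adjusted over the list alone, adjusted p = 0.403), with Vegfa, an angiogenic growth factor, at 0.53, Mxi1 at 0.43 and Ndrg1 at −0.48. Cholesterol synthesis genes were lower for 1 of 21 (1, adjusted p = 0.224), the sterol reductase gene Tm7sf2 at −0.38. Matrix and adhesion genes were higher for 1 and lower for 3 of 32 (3 and 9, adjusted p = 0.235), with Anxa5 at −0.52, Lama1 at −0.29 and Ccn1 at 0.32. Fibroblast genes, which mark feeder cells, were lower for 2 of 27 (2, adjusted p = 0.552), the smooth muscle genes Acta2 at −0.70 and Tagln at −0.34, while the collagen gene Col1a1, chosen after its value was seen, was at −0.02 and not called. Genes of the unfolded protein and amino acid response were higher for 1 of 26 (1, adjusted p = 0.925), Ddit4 at 0.38, and heat shock genes for 1 of 13 (1, adjusted p = 0.505 in camera and 0.0139 in fry), Hsph1 at 0.33. Housekeeping genes were higher for 1 of 13 (1, adjusted p = 0.655), Tfrc at 0.24. Hox genes were called for 0 of 36 (adjusted p = 0.873) and ribosomal protein genes for 0 of 21 (adjusted p = 0.655), each 0 over the list alone in limma. Each of these lists had 1 gene at an unadjusted p under 0.05 and 0 calls with a trended prior or without moderation. The Hox genes had mean log2 levels from 3.90 to 6.90, so the lack of calls says little for the dim ones. Among the called genes of lists that were not described at length, Pax6, H2bc4, Lefty1, Inhbb, Egr1, Igf2, Vegfa, Ndrg1, Tm7sf2 and Acta2 stayed called with any array left out. The mean, median and test of the G1/S, Hox and imprinted lists did not share a sign.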

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

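All alternatives were planned. Trim71 kept its direction and its call under every alternative that gave a value, with a log2 fold change between −1.51 and −1.55, and no called gene or list that is named changed direction. Counts of genes moved. They were 171 higher and 108 lower with the replicate number as a block, 1080 and 737 in the bright part of the probe sets, 1213 and 854 with a trended and robust prior, 1114 and 1058 with array weights, and 271 and 142 without moderation. Over all probe sets, including those without 1 symbol, they were 266 and 134, at least 1.5-fold 62 and 43, and at an adjusted p under 0.01 152 and 94. Lower genes numbered 763 after a repeated quantile normalization, and 955 of the 1103 genes called were shared with the fit on centred arrays. With each array left out in turn, higher genes ranged from 148 to 603, lower genes from 101 to 699 and called lists from 0 to 7. The highest counts for higher and lower genes and the lowest for lists all came without knockdown array 3, with 936 shared calls. Called lists numbered 0 in the bright part of the probe sets (5 of 28 at an unadjusted p under 0.05), 0 with array weights (7), 0 without knockdown array 3 (7), 0 with an estimated correlation (1), 1 without moderation and 10 in fry. A fit of 5 arrays has fewer samples, and the stricter thresholds keep fewer genes by construction. Camera with an estimated correlation has fewer degrees of freedom than with the preset one. Fewer samples do not account for the increase of lower genes from 428 to 699 without knockdown array 3. For that fit and the other settings the cause was not tested. The share of higher genes, 61.2%, was 50.5% after quantile normalization, 46.1% with centred arrays and 46.3% without knockdown array 3, and the median change of all genes went to −0.01 and −0.03 in the first 2. Same-numbered control and knockdown arrays had correlations of −0.02, −0.15 and −0.24 between their deviations from the group means. No deviation shared by replicate number was seen, but with 3 arrays per group these values cannot exclude a pairing. The block result, 275 of whose 279 calls were shared, says nothing of the size of the effects. Signal over background could not be assessed without detection calls. Over named genes, 1557 of the values under the alternatives stayed on their side of the threshold, 336 no longer passed it and 47 newly passed it, and for lists the counts were 388, 154 and 27.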

Other observations

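The tests of cell composition and of transfection below were chosen after the results were seen, and the lists of epithelial, Hedgehog and oocyte genes were written after the 60 genes with the smallest p-values had been read. Each was tested on the members not among those 60. Epithelial genes encode junction proteins, keratins and the regulators of epithelial splicing and transcription. Of 30 such genes, 28 had a positive log2 fold change, 6 rose, 0 fell and 24 did not pass. The camera p was 2.13e-10 in limma (adjusted p = 6.39e-10 over 3 lists) with the preset correlation, and p = 0.0638 with an estimated correlation, which misses the threshold. Elf3, a transcription factor, rose by 0.60, Esrp2, a splicing regulator, by 0.51, the vesicle transport gene Rab25 by 0.46, the claudin gene Cldn7 by 0.40, the grainyhead factor gene Grhl3 by 0.35 and Tjp3 by 0.23, and Elf3 and Rab25 were called with any array left out. The members already read, Esrp1 at 0.75, Erbb3 at 0.68, Lad1 at 0.64 and Grhl2 at 0.57, had been picked for their changes. The mean log2 level of the 30 was 8.28 ± 0.034 in the control and 8.48 ± 0.053 in the knockdown cells (SD, n = 3), a shift of 0.20.

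That epithelial genes rise together after the knockdown may be offered only as a hypothesis, tested with camera. The preset p of 2.13e-10 passed, and the p of 0.0638 with an estimated correlation did not. That version of camera changes both the correlation and the degrees of freedom. It therefore cannot show that correlation between these genes ended the call. With each array left out the preset camera p lay between 5.38e-11 and 1.7e-07, it was 9.4e-11 and 4.42e-11 after quantile normalization and centring, and fry gave 0.00553. Of the 30 genes, 5 stand in the fixed lists, among them Krt8 and Krt18, which are also in the trophectoderm list. Trophectoderm is an epithelium, and 3 of the 18 genes of its list rose on the same arrays, Tfap2c at 0.53, Fgfr2 at 0.49 and Gata2 at 0.38, while the 15 others had a mean of 0.05. The list had an adjusted p = 0.757 with an estimated correlation, 0.0744 without knockdown array 2 and 0.0923 without knockdown array 3, and a change in the kinds of cell stays open here too. No technical explanation specific to this list was tested.

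Of Hedgehog readouts, Ptch1 at 0.80, Gli1 at 0.64 and Ccnd2 at 0.79 had been read first. The 12 others did not pass as a list (camera p 0.0882, adjusted p = 0.132), with 1 higher, Prdm1 at 0.37. Oocyte genes were looked at because of Zp3 and Khdc3. The 19 others did not pass (camera p 0.398), with Kit at 0.38 and Ooep at 0.34 higher and a list median of −0.04.

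More genes were called higher than lower. The share of higher calls was 50.5% after quantile normalization and 46.3% without knockdown array 3, so the excess depends on both. In both, lower calls increased, from 428 to 763 and to 699, while higher calls numbered 675 and then 779 and 603, and with arrays centred on their medians (46.1% higher) lower calls increased to 616 and higher calls decreased to 527. These values do not show that scaling or array 3 produced the higher calls, and scaling, that array and the knockdown itself stay open as sources of the excess.

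Knockdown array 3 lay farthest from its group. Its scaling is not the whole cause, because its deviation was 0.105 after quantile normalization against at most 0.0882 on the other arrays. Its slope on the mean change of the other knockdown arrays was 0.849 over 1302 genes. The other 2 arrays had slopes of 0.89 over 654 genes and 0.949 over 344 genes. The slope of array 3 was the lowest but lay within the margin of 0.2 set beforehand. The slopes share the control arrays and rest on different genes, so they cannot decide whether its response was somewhat weaker. What set the array apart was not found.

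The naive pluripotency list was called higher with the preset correlation and not with an estimated one (adjusted p = 0.778), while the primed and neural lists had negative means that did not pass in camera and of which fry called the primed (adjusted p = 0.0472) and not the neural (adjusted p = 0.0637). Whether fewer differentiated cells of all kinds lowered their markers was read from the mean changes of 5 lists. These were 0.12 for trophectoderm, −0.07 for neural, −0.03 for mesoderm, −0.0043 for endoderm and −0.04 for fibroblast genes. The means differed among the lists (permutation p = 0.0156 over genes, which are not independent replicates). They cannot decide the question, because the lists mix bright and dim members. Mean log2 levels reached 11.4 for Sparc but only 3.37 for Tpbpa, chosen after its value was seen. Bright members may be expressed by the stem cells themselves, and the dimmest could hardly fall. The trophectoderm and neural means, a pair picked after their directions were seen, differed by 0.19 with a standard error of 0.071 over genes, but among the 15 and 16 genes not called by 0.07 with one of 0.05 (permutation p = 0.161), so this difference rests on few genes. Transfection of the knockdown cells alone, which the labels leave open, cannot be told apart from the knockdown, since both would fall on the same arrays, and the interferon list (camera p 0.122) does not separate them. Fewer differentiated cells, a change in their kinds, effects of the siRNAs on transcripts other than Trim71 and an effect of Trim71 itself stay open. All but the first are untested.

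The 6 arrays allow 10 splits into 3 and 3, which are too few for a share under 0.05. The real split gave 1103 genes and 1 of the 10 splits reached that number. The highest of the others gave 0 genes in limma, with up to 1933 genes at an unadjusted p under 0.05 against 3794 in the real split. The split with 1933 set control arrays 1 and 2 and knockdown array 3 against the rest. Every other split mixes control and knockdown arrays, so any group difference widens its spread. Its 0 calls are therefore no measure of chance.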
